A study of Homo sapiens with 6 samples.

How the data were processed

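The data are RNA-seq libraries from A375 melanoma cells, 3 from wild-type and 3 from DUS1L knockout cells. Per the labels' protocols, total RNA was extracted with TRIzol, samples passed a minimum RNA integrity number, and paired-end libraries were sequenced at a commercial provider on a BGISEQ instrument. Knockout cells were made by CRISPR/Cas9 editing of the DUS1L locus and clonal selection, per the labels' protocols, and wild-type cells were kept without targeting. The guide sequence, the edited alleles and the number of clones were not given in the sources used here.

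The authors deposited 1 table of estimated counts per gene with a column for each library, and its values are expected counts that need not be whole. Between 23.6% and 24.8% of genes in a library had a fractional value, which arises where reads that fit several genes or transcripts are divided among them. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release were not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart. No normalization was recorded for the deposited estimated counts, and their totals differed between libraries, from 17121315 to 18861514. The table lists 63086 genes by Ensembl identifier, of which 62541 (99.1%) matched GENCODE release 44 by identifier without version and 61547 matched with the same version. Gene symbols, biotypes and coordinates come from that release.

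Estimated counts were rounded to whole numbers. A count of 3 in a library corresponds to 0.16 to 0.18 CPM, which sets the lowest level that could be read, and this covers counting error only. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 16046 genes and set aside 14298 genes with a count in some library. Library sizes were scaled by the TMM method, and CPM values use the scaled library size. Knockout and wild-type groups, taken from the sample titles, were compared with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood fit with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fitted value and its F statistic. A further test on the same fit (glmTreat) asked whether a change was larger than 1.5-fold. All tests are two-sided. No pair of libraries matched within sampling noise, with chi-square values per degree of freedom from 3.77 to 7.24 within groups and from 34.2 to 50.4 between groups, so none was treated as a repeat deposit of another. This does not show that the libraries come from separate cultures, which rests on the series description.

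Before the data were examined, 40 gene lists were fixed. They cover the dihydrouridine synthases, other tRNA modification enzymes, cytosolic and mitochondrial aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, ribosome biogenesis, translation initiation and elongation factors, mitochondrially encoded proteins, nuclear oxidative phosphorylation, stress, signalling, metabolic, cell cycle, melanoma and matrix programs, and markers of keratinocytes, epithelium, fibroblasts, leukocytes and endothelium. Their members were matched by symbol, and 4 members had no match. Lists with 5 or more tested members were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 37 lists tested, and again with a correlation estimated per list. Camera compares a list with all other genes. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, was an alternative. The genes of each chromosome with 20 or more tested genes were tested with camera in the same way, and genes within 1 Mb of DUS1L were listed.

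The rule for the genes named was also set before the data were examined. It takes DUS1L and, among called protein-coding genes whose groups do not overlap and whose higher group has a mean of 5 CPM or more, the 8 highest and the 8 lowest log2 fold changes and, of the rest, the 4 higher and 4 lower genes with the smallest p. It adds up to 4 members of each list with the smallest p, and all 4 dihydrouridine synthases. Some genes that the rule takes are not reported here. Genes next to DUS1L were named after their values were seen.

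The procedure was tested on simulated counts with the means and library sizes of this comparison over 16046 genes, of which 200 were changed. At an adjusted p under 0.05, it recovered 42%, 64%, 70% and 92% of the genes changed by 1.25-fold, 1.5-fold, 2-fold and 4-fold. There were 8 calls among unchanged genes, 5.6% of the calls. A far smaller share of genes was changed than was called in the data, which makes the adjustment of p stricter, so recovery in the data may differ. In a separate simulated draw, in which genes were independent, camera called 3 of 3 shifted lists and none of 30 unchanged lists. The shifted lists all moved by the same amount, so this does not cover smaller shifts.

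Alternatives were DESeq2 size factors (the RLE method) in edgeR, upper quartile scaling, library size alone, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, replicate number as a block, and each library left out in turn. A correction of each library for transcript length and GC content, by a loess fit on the longest transcript per gene, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.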

Results

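RNA from A375 cells, an established human melanoma line that carries an activating BRAF mutation, was sequenced from wild-type cells and from cells in which DUS1L had been disrupted with CRISPR/Cas9. DUS1L encodes a dihydrouridine synthase, an enzyme that reduces uridine to dihydrouridine in the D loop of tRNAs. The comparison asks which transcripts differ between DUS1L knockout and wild-type cells. Each genotype had 3 libraries, described by the submitters as biological replicates, and the libraries held between 17121315 and 18861514 estimated counts. Knockout cells had passed through clonal selection and wild-type cells had been kept in parallel without targeting. The number of clones was not stated, so every difference between the genotypes also holds any difference between a clone and the parental population. The first principal component, with 53.1% of the variance, separated the genotypes. Wild-type replicate 1 lay at 31.6 on the second component (13.7% of the variance), against -15.5 and -16.3 for the other wild-type libraries. Mitochondrially encoded transcripts took 4.58% ± 0.18 of the counts in wild-type and 3.91% ± 0.17 in knockout cells (SD, n = 3 each).

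The DUS1L transcript was lower in each knockout library than in each wild-type library. Its level was 79.95, 75.7 and 77.0 CPM (counts scaled to library size) in the wild-type libraries and 55.4, 54.7 and 53.1 CPM in the knockout libraries. This amounts to a 1.43-fold lower level (log2 fold change -0.51, SE 0.06, adjusted p = 1.69e-06, edgeR quasi-likelihood test), so 70.2% of the wild-type transcript level was left. An edit that shifts the reading frame need not lower the transcript, and gene counts do not show the edited bases. DUS1L (ENSG00000169718.18) lies on the minus strand of chromosome 17 from 82057506 to 82065887 (GRCh38). Of the other dihydrouridine synthases, DUS4L was higher in knockout cells, at 16.8 ± 1.4 against 12.5 ± 1.8 CPM (adjusted p = 0.00794). That call was lost without wild-type replicate 2 (log2 fold change 0.31, adjusted p = 0.0676). DUS2 was at 20.3 ± 0.4 CPM in wild-type and 21.6 ± 0.9 CPM in knockout cells (adjusted p = 0.463), and DUS3L at 47.3 ± 2.0 and 49.9 ± 5.8 CPM (adjusted p = 0.464). Adjusted over the list alone, the 4 synthases gave 1 higher and 1 lower gene as well.

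Within 1 Mb of DUS1L, 66 other genes were tested, of which 12 were higher in knockout cells, 26 were lower and 28 were not called. Their median log2 fold change was -0.23 (SD 0.80 over genes), and -0.179 after correction for transcript length and GC content, an alternative chosen after seeing the data. The genes next to DUS1L went the same way as it did. In the stretch from CENPX, which starts at 82018702, to FASN, which ends at 82098294, all 8 consecutive protein-coding genes with a mean of 5 CPM or more had a negative log2 fold change, and 7 of them were called lower. The neighbours in that stretch were chosen after their values were seen, and the genome held 50 runs of as many or more such genes below 0. GPS1, which lies tail to tail with DUS1L on the opposite strand, fell by 0.29 on the log2 scale (adjusted p = 0.00021) and RAC3 fell by 0.83 (adjusted p = 4.02e-05). RFNG, at log2 fold change -0.19, was not called (adjusted p = 0.145). After the same correction, CENPX and DCXR were not called either (adjusted p = 0.113 and 0.0605), while FASN had a smaller p (log2 fold change -0.406, adjusted p = 1.48e-06, against -0.372 and 0.0395). Some of these calls were also lost when a library was left out, which leaves fewer libraries to test. CENPX was not called without wild-type replicate 2 or knockout replicate 2 (adjusted p = 0.0643 and 0.059), nor DCXR without knockout replicate 2 or 3 (adjusted p = 0.053 and 0.0585). FASN was not called without wild-type replicate 2 (adjusted p = 0.105), without knockout replicate 1, 2 or 3 (adjusted p = 0.0661, 0.0985 and 0.073), or with library size alone as the scaling (adjusted p = 0.0732).

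**Figure D1:**
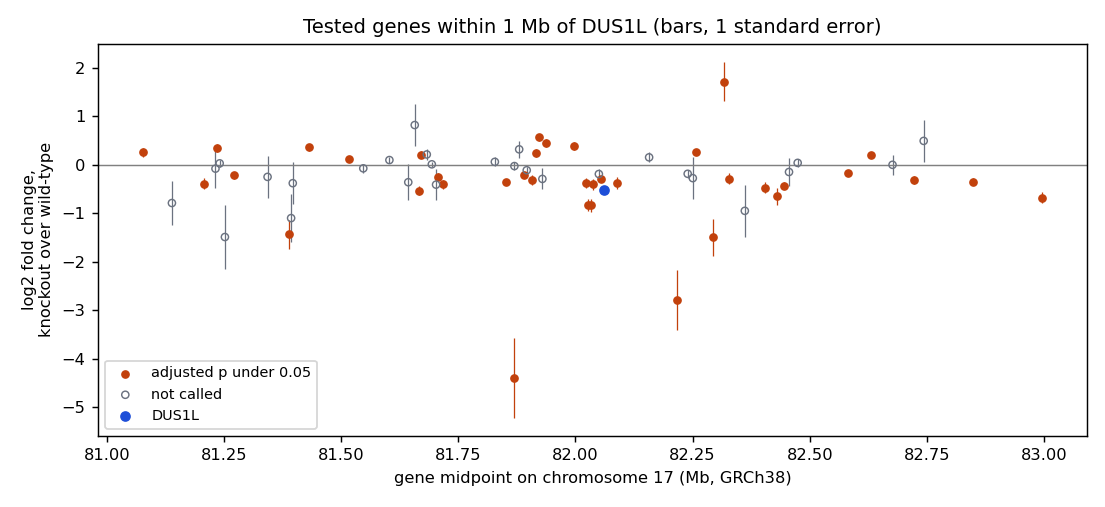
Log2 fold change (knockout over wild-type, bars 1 standard error) of each tested gene within 1 Mb of DUS1L against its midpoint on chromosome 17 in Mb. Filled orange points passed the adjusted p threshold of 0.05, open grey points did not, and the blue point is DUS1L at -0.51; 12 neighbours are higher and 26 lower.

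Across the transcriptome, 3288 of 16046 tested genes were higher and 3320 were lower in DUS1L knockout cells at an adjusted p under 0.05 (edgeR), together 41.2% of the genes tested. Most changes were small. The median call was 1.34-fold and 68.7% of calls were under 1.5-fold. When the test asked for a change of more than 1.5-fold, 371 genes were higher and 204 were lower. With DESeq2 these counts were 207 and 95, and with limma-voom 231 and 115, each by that program's own test against 1.5-fold. The 3 knockout values lay wholly on one side of the 3 wild-type values in 51.1% of tested genes, against 10% by chance. The spread between replicates was narrow, with a common biological coefficient of variation of 7.12%. The p-values measure the spread between these cultures. Because the clones are not stated, it is not known whether that includes any spread between independently edited clones.

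Heat shock proteins and cytokines were among the genes with the highest fold changes. HSPA6, a strictly stress-inducible chaperone, rose from 13.8 ± 10.4 to 233.3 ± 53.5 CPM (log2 fold change 4.08, SE 0.55, adjusted p = 0.00534). Its wild-type mean rests largely on replicate 3, and without that library the log2 fold change was 4.876 (adjusted p = 0.00287). With replicate number as a block HSPA6 was not called (log2 fold change 4.135, adjusted p = 0.0608). The inducible chaperone genes HSPA1A and HSPA1B rose by 2.80 and 2.68 on the log2 scale, but their sequences are nearly identical and the split of reads between them is uncertain. CSF2, which encodes the cytokine GM-CSF, rose from 2.69 ± 0.92 to 21.2 ± 3.4 CPM, and the neutrophil-attracting chemokines CXCL2 and CXCL3 reached 74.0 ± 17.2 and 39.3 ± 4.3 CPM from 12.01 ± 3.31 and 6.37 ± 2.39 CPM. The latter pair also have closely related copies. TNFSF14, a TNF family ligand, and C15orf48, a mitochondrial protein gene, rose by 2.77 and 2.53 on the log2 scale from under 2 CPM. The smallest p among higher genes belonged to HMOX1, the inducible heme oxygenase, which rose from 25.4 ± 2.8 to 128.4 ± 2.6 CPM (adjusted p = 9.96e-15). HSPH1 and BAG3, partners of the HSP70 chaperones, and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, followed it by p. HSPH1 rose from 443.4 ± 16.98 to 1038 ± 42 CPM and BAG3 from 212.1 ± 12.4 to 499.2 ± 12.3 CPM.

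The transcription factor genes PRRX1 and SOX2 and the hyaluronan synthase gene HAS2 were among the genes with the lowest fold changes. PRRX1, a mesenchymal homeobox factor, fell from 176.3 ± 20.6 to 38.4 ± 2.6 CPM (log2 fold change -2.20, SE 0.08, adjusted p = 1.5e-11). MEOX2, another homeobox factor, fell from 109.9 ± 3.9 to 31.1 ± 2.6 CPM, and the stem cell factor SOX2 from 14.6 ± 2.3 to 3.61 ± 0.58 CPM. HAS2 fell from 7.53 ± 1.41 to 1.32 ± 0.33 CPM, and SDC3, a cell surface proteoglycan, from 220.7 ± 11.3 to 78.9 ± 1.9 CPM. GAP43, which encodes a growth cone protein, fell by 2.26 on the log2 scale. ART3, MYH15, the pseudokinase gene TRIB2 and the mitotic kinesin gene KIF20A fell by 2.04, 1.87, 1.53 and 1.51. AKR1C2 fell by 2.00, and its close relatives in the same gene cluster can share reads with it. CT45A7, a member of a cancer testis antigen family with near-identical copies on the X chromosome, was at 8.29, 15.9 and 10.2 CPM in wild-type libraries and at 0, 0.40 and 0 CPM in knockout libraries (adjusted p = 0.00044). How reads were divided among the copies of that family was not given, so its value is uncertain.

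**Figure D2:**
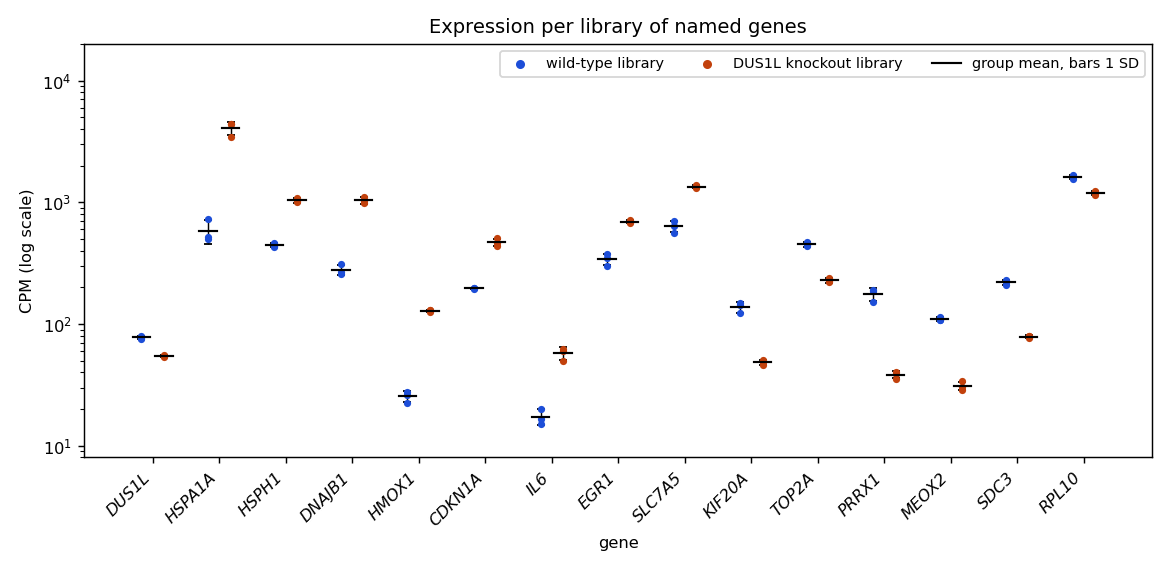
Expression per library of 15 named genes in CPM on a log scale, with wild-type libraries in blue, DUS1L knockout libraries in orange, horizontal lines at the group means and bars of 1 SD (n = 3 each). The 3 knockout libraries lie wholly above or below the 3 wild-type libraries for each gene shown, for example 25.4 against 128.4 CPM on average for HMOX1 and 176.3 against 38.4 CPM for PRRX1.

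The heat shock, immediate early, inflammatory and integrated stress response lists were called higher. Of the 37 lists large enough for camera, a test of whether a list's genes move more than other genes, 21 were called, 9 up and 12 down. With the correlation between genes estimated per list in place of the preset 0.01, heat shock was the one list still called. For each other list that was called, the adjusted p with an estimated correlation is given as well. In the heat shock list, 13 of 14 genes rose (13 adjusted over the list alone, median log2 fold change 0.90, camera adjusted p = 9.71e-36, and adjusted p = 0.0226 with an estimated correlation). DNAJB1, a cochaperone of HSP70, rose from 279.0 ± 28.7 to 1040 ± 63 CPM, and DNAJA1 rose from 390.5 ± 19.8 to 640.1 ± 16.9 CPM. All 14 immediate early genes rose (14 adjusted over the list alone, median 0.89, camera adjusted p = 1.44e-24, adjusted p = 0.107 with an estimated correlation). EGR1 rose from 340.8 ± 38.3 to 694.9 ± 19.1 CPM, FOSB from 22.5 ± 1.0 to 60.7 ± 4.9 CPM, and ZFP36, which encodes an mRNA decay factor, from 53.3 ± 1.9 to 126.4 ± 12.2 CPM.

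Inflammatory cytokines and NF-kB targets rose in all 26 tested members (26 adjusted over the list alone, median 1.11, camera adjusted p = 8.25e-39, adjusted p = 0.107 with an estimated correlation), and 18 of them rose by more than 1.5-fold. The cytokine gene IL6 rose from 17.3 ± 2.6 to 57.5 ± 6.7 CPM, NFKB2 from 252.9 ± 21.1 to 479.2 ± 28.2 CPM, and the adhesion receptor gene ICAM1 from 177.3 ± 14.8 to 341.4 ± 23.5 CPM. Summed leukocyte markers were at 39.3 ± 2.5 CPM in wild-type and 37.6 ± 4.8 CPM in knockout libraries, most of it from CD68 and CORO1A in both genotypes. The 9 leukocyte markers left out by the count filter rose from 0.189 ± 0.064 to 1.12 ± 0.38 CPM. The filter was applied over both genotypes, so it also limits how high these markers can be in knockout libraries. Summed epithelial markers were at 528.2 ± 26.5 and 619.5 ± 13.97 CPM, of which KRT18 made up the most in both genotypes. Targets of the integrated stress response, the translational control program that acts through ATF4, rose in 26 of 31 tested members and fell in 1 (27 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 2.24e-21, adjusted p = 0.107 with an estimated correlation). The 2 chains of an amino acid exchanger rose alike, SLC7A5 by 1.08 (SE 0.06) and SLC3A2 by 1.08 (SE 0.06) on the log2 scale. Asparagine synthetase, ASNS, rose from 107.1 ± 7.4 to 188.7 ± 11.7 CPM, and the secreted glycoprotein gene STC2 from 42.8 ± 5.2 to 92.0 ± 3.5 CPM.

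Targets of p53 rose in 25 of 29 tested members and fell in 2 (26 and 2 adjusted over the list alone, median 0.68, camera adjusted p = 1.23e-24, adjusted p = 0.0887 with an estimated correlation). CDKN1A rose from 197.1 ± 1.7 to 468.6 ± 34.0 CPM, BTG2, an antiproliferative factor, from 25.6 ± 1.2 to 64.1 ± 3.9 CPM, and ZMAT3 from 28.5 ± 1.3 to 65.3 ± 4.8 CPM. Targets of YAP/TAZ, the effectors of Hippo signalling, rose in 17 of 24 members and fell in 2 (17 and 2 adjusted over the list alone, median 0.54, camera adjusted p = 1.44e-10, adjusted p = 0.107 with an estimated correlation). AMOTL2 rose from 105.1 ± 6.2 to 231.5 ± 5.5 CPM and NUAK2 from 20.6 ± 2.8 to 47.5 ± 6.0 CPM. Cytosolic aminoacyl-tRNA synthetases rose in 11 of 23 members and fell in 1 (11 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.0214, adjusted p = 0.365 with an estimated correlation), led by YARS1 and GARS1, which rose by 0.62 each. Autophagy and lysosome genes rose in 11 of 32 members and fell in 4 (12 and 4 adjusted over the list alone, median 0.10, camera adjusted p = 0.0248, adjusted p = 0.267 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 1224 ± 22 to 2213 ± 37 CPM and MAP1LC3B, an autophagosome coat protein gene, rose by 0.74 on the log2 scale, whereas the lysosomal protease gene CTSZ fell by 0.73. Without wild-type replicate 3, the synthetase list had an adjusted p of 0.0537 and the autophagy list an adjusted p of 0.066.

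The undifferentiated invasive melanoma program was called up with members in both directions, 15 higher and 11 lower of 31 (15 and 11 adjusted over the list alone, median 0.21, camera adjusted p = 0.0195, adjusted p = 0.267 with an estimated correlation). IL6, the actin-binding protein gene TPM1 and the AP-1 member FOSL1 rose by 1.74, 0.78 and 0.54 on the log2 scale, and fibronectin, FN1, fell by 0.62. Melanocyte differentiation genes were not called by camera (median -0.02, adjusted p = 0.069), with 1 of 17 tested members higher and 6 lower (1 and 6 adjusted over the list alone). The list has 27 members. Those left untested for low counts include the pigmentation genes TYR, DCT, PMEL and MLANA, with at most 9 counts in any library, so the result does not cover them. The receptor genes ERBB3, EDNRB and MC1R fell by 0.86, 1.11 and 0.56, and the lineage factor SOX10 fell from 603.8 ± 16.9 to 480.6 ± 33.8 CPM. Without knockout replicate 2, that list had an adjusted p of 0.0345.

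Genes of the cell cycle were lower in knockout cells. All 35 mitosis genes fell (35 adjusted over the list alone, median log2 fold change -0.81, camera adjusted p = 1.07e-57, adjusted p = 0.0577 with an estimated correlation), and 21 of them fell by more than 1.5-fold. KIF20A fell from 137.9 ± 13.6 to 48.5 ± 2.5 CPM, topoisomerase TOP2A from 451.9 ± 19.8 to 228.9 ± 10.7 CPM, the kinetochore protein gene CENPF from 328.2 ± 11.3 to 173.7 ± 5.4 CPM, and the spindle protein gene DLGAP5 from 100.6 ± 1.0 to 49.6 ± 1.7 CPM. DNA replication and S phase genes fell in 29 of 40 members and rose in none (31 lower adjusted over the list alone, median -0.32, camera adjusted p = 1.07e-07, adjusted p = 0.172 with an estimated correlation), and none passed the test against 1.5-fold. RRM1, TYMS and MCM3, which supply nucleotides or license replication origins, fell by 0.52, 0.39 and 0.44 on the log2 scale.

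Transcripts for cytosolic ribosomal proteins fell by small amounts, with 70 of 79 lower and 1 higher (74 and 2 adjusted over the list alone, median -0.28, range -0.488 to 0.123, camera adjusted p = 2.98e-15, adjusted p = 0.267 with an estimated correlation). Many have processed pseudogenes that can share reads. RPL10 fell from 1616 ± 64 to 1192 ± 42 CPM and RPS25 from 772.5 ± 47.5 to 583.8 ± 22.5 CPM. Nuclear oxidative phosphorylation subunits fell in 38 of 55 members and rose in none (40 lower adjusted over the list alone, median -0.23, camera adjusted p = 1.49e-07, adjusted p = 0.248 with an estimated correlation), with ATP5F1E and UQCRC2 falling by 0.53 and 0.42. Mitochondrially encoded proteins fell in 9 of 13 members and rose in 1 (10 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 0.00099, adjusted p = 0.367 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, fell from 11924 ± 829 to 8559 ± 184 CPM. That list's call was lost after correction for transcript length and GC content, an alternative chosen after seeing the data (adjusted p = 0.188, median -0.08).

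Hypoxia and glycolysis genes fell in 19 of 35 members and rose in 7 (19 and 7 adjusted over the list alone, median -0.26, camera adjusted p = 0.00414, adjusted p = 0.453 with an estimated correlation). The glycolytic enzyme genes GAPDH and ENO1 fell by 0.48 and 0.43 on the log2 scale. Fatty acid synthesis genes fell in 10 of 16 members and rose in 1 (10 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.00243, adjusted p = 0.107 with an estimated correlation). SREBF1, which encodes a regulator of lipid synthesis, fell from 99.9 ± 13.6 to 59.0 ± 5.1 CPM, and the desaturase genes SCD and FADS1 fell by 0.45 and 0.44. Genes of the unfolded protein response fell in 12 of 21 members and rose in 5 (13 and 5 adjusted over the list alone, median -0.23, camera adjusted p = 0.0138, adjusted p = 0.387 with an estimated correlation). The members that fell include chaperones of the endoplasmic reticulum. PDIA4 fell from 916.1 ± 40.3 to 511.8 ± 20.8 CPM, and HSP90B1 and CALR fell by 0.67 and 0.49, whereas the stress sensor gene ERN1 rose from 15.95 ± 3.16 to 38.6 ± 2.5 CPM.

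Matrix and adhesion genes were lower on balance. Extracellular matrix and collagen genes fell in 23 of 41 members and rose in 6 (23 and 6 adjusted over the list alone, median -0.25, camera adjusted p = 2.12e-05, adjusted p = 0.107 with an estimated correlation). The laminin genes LAMB1 and LAMA4 and the protease inhibitor gene TIMP3 fell by 0.62, 0.94 and 0.76 on the log2 scale, and a further laminin gene, LAMB3, rose by 0.86. Integrins and focal adhesion genes fell in 12 of 28 members and rose in 2 (13 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.00177, adjusted p = 0.242 with an estimated correlation), with ITGA6 falling from 374.1 ± 19.9 to 204.5 ± 11.2 CPM. Neural and axon guidance genes fell in 12 of 27 members and rose in 3 (12 and 4 adjusted over the list alone, median -0.24, camera adjusted p = 0.0145, adjusted p = 0.248 with an estimated correlation), with SEMA3C and EPHA3 falling by 0.69 and 0.84. Fibroblast markers were called down with 2 of 10 members lower, PRRX1 and PDGFRB (2 adjusted over the list alone, median -0.17, camera adjusted p = 0.0402, adjusted p = 0.242 with an estimated correlation). That call was lost without knockout replicate 1 (adjusted p = 0.0906). COL1A1 and COL1A2 varied within the groups, with COL1A1 at 19.4 ± 16.8 CPM in wild-type and 52.9 ± 41.5 CPM in knockout cells (adjusted p = 0.311, and 0.0337 with limma-voom, in a range of 0.0337 to 0.697 over the alternatives).

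**Figure D3:**
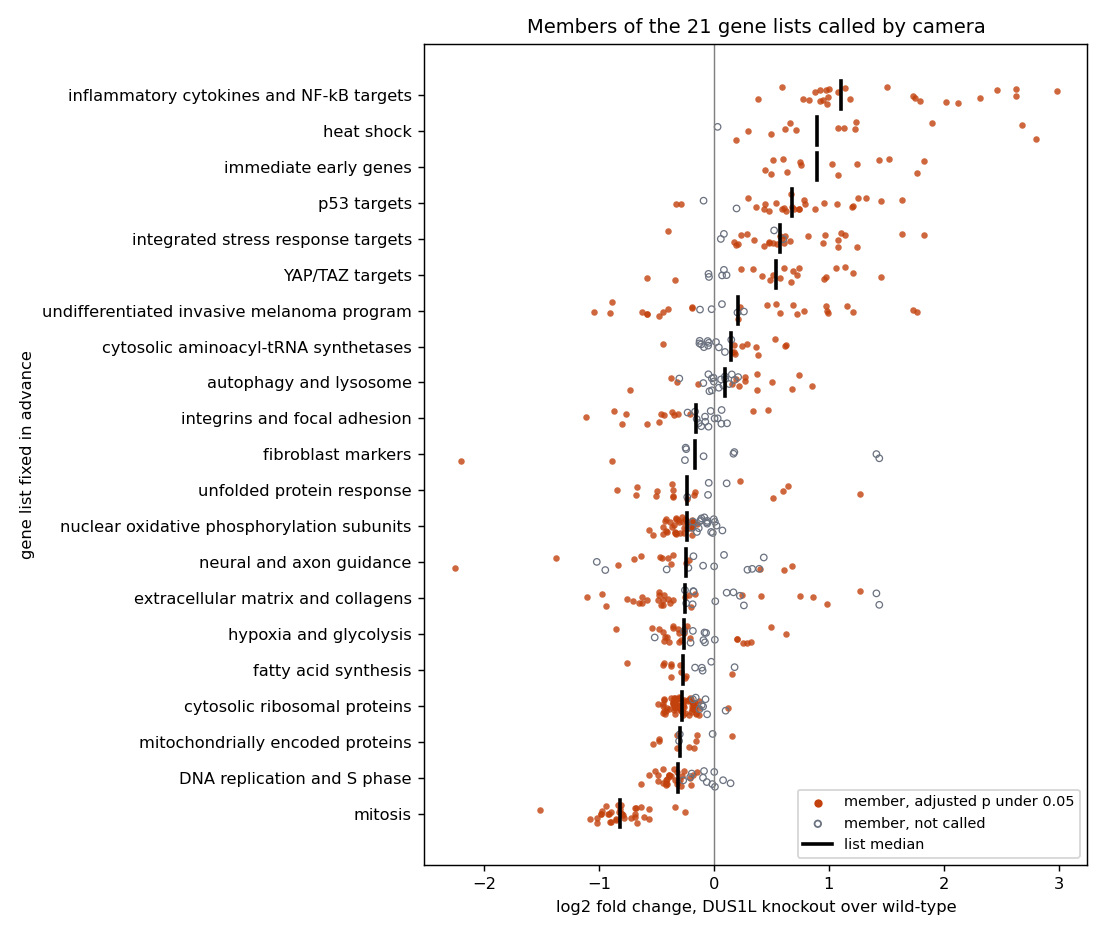
Log2 fold change (knockout over wild-type) of each tested member of the 21 lists called by camera, one row per list and sorted by the list median, which is the black bar. Filled orange points are members with an adjusted p under 0.05 and open grey points are not; inflammatory cytokines and NF-kB targets have the highest median, 1.11, and mitosis the lowest, -0.81.

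The other lists were not called by camera. The other tRNA modification enzymes had 19 higher and 6 lower of 70 members (18 and 5 adjusted over the list alone, median 0.07, adjusted p = 0.163), with YRDC at log2 fold change 0.46 and URM1 at -0.33. Mitochondrial aminoacyl-tRNA synthetases had 6 lower of 17 (6 adjusted over the list alone, median -0.10, adjusted p = 0.0608, and adjusted p = 0.0475 without knockout replicate 3), with IARS2 at -0.51. Ribosome biogenesis had 13 higher and 9 lower of 43 (13 and 9 adjusted over the list alone, adjusted p = 0.454), with NIP7 at 0.45 and NPM1 at -0.38. Translation factors had 7 higher and 15 lower of 43 (7 and 15 adjusted over the list alone, adjusted p = 0.482), with EIF3I at 0.37 and EEF1A1 at -0.34. MAPK output genes had 8 higher and 9 lower of 22 (9 and 9 adjusted over the list alone, adjusted p = 0.482), with EPHA2 and DUSP5 at 1.05 and 0.94 and ETV4 at -0.76. Interferon response genes had 15 higher and 10 lower of 37 (17 and 10 adjusted over the list alone, adjusted p = 0.086), with IRF1 at 0.99 and IFITM3 at -0.46. That list had an adjusted p of 0.0111 without wild-type replicate 1 and of 0.0272 without knockout replicate 2.

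TGF-beta targets had 10 higher and 6 lower of 20 (10 and 6 adjusted over the list alone, adjusted p = 0.0739, and adjusted p = 0.0476 without knockout replicate 3), with ID1 at log2 fold change -0.74. MYC targets had 5 higher and 10 lower of 28 (6 and 11 adjusted over the list alone, adjusted p = 0.454), with ODC1 at 0.45. Cholesterol biosynthesis had 3 higher and 7 lower of 24 (3 and 7 adjusted over the list alone, adjusted p = 0.139), with HMGCS1 at 0.67 and FDFT1 at -0.46. MHC class I antigen presentation had 5 higher and 2 lower of 17 (5 and 3 adjusted over the list alone, adjusted p = 0.715), with TAP1 at 0.57 and PSME1 at -0.29, and its median of -0.02 and mean of 0.04 differed in sign. The NRF2 and glutathione list had 7 higher and 8 lower of 23 (8 and 10 adjusted over the list alone, adjusted p = 0.703), with HMOX1 and AKR1C2 at its ends, and its median of -0.05 also differed in sign from its mean of 0.00 and its upward camera direction. Cancer testis antigens had 3 higher and 2 lower of 14 (4 and 2 adjusted over the list alone, adjusted p = 0.84), with PRAME at -0.44 and MAGEA3, one of a family of close copies, at 0.18. Replication-dependent histones had 1 higher and 1 lower of 13 (none adjusted over the list alone, adjusted p = 0.703).

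Keratinocyte markers had 1 higher of 7 tested (none adjusted over the list alone, adjusted p = 0.61) and summed to 71.3 ± 5.0 CPM in wild-type and 73.3 ± 6.9 CPM in knockout libraries. Endothelial markers had 1 higher and 1 lower of 5 (1 and 1 adjusted over the list alone, adjusted p = 0.911), with a median of 0.02 against a mean of -0.13, and summed to 10.3 ± 1.2 and 11.2 ± 0.4 CPM. Epithelial and leukocyte markers, with 4 tested members each, were too few for camera. Among epithelial markers KRT7 and KRT18 rose by 1.41 and 0.22 on the log2 scale and CLDN4 fell by 0.72, and among leukocyte markers CORO1A fell by 0.50, each also when adjusted over the list alone. Fibroblast markers summed to 263.9 ± 17.3 CPM in wild-type and 172.5 ± 56.9 CPM in knockout libraries, a fall carried by PRRX1. The sum of the others was 58.0, 82.5 and 122.2 CPM in wild-type and 98.4, 202.7 and 101.4 CPM in knockout libraries. An exact two-sided permutation test of such sums cannot give a p below 0.1 with 3 libraries against 3.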

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

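The length and GC correction was chosen after seeing the data, and the other alternatives were planned. DUS1L stayed lower and past the threshold in all 15 alternatives, with log2 fold changes from -0.532 to -0.466. The counts of 3288 higher and 3320 lower genes stayed within 1.5 times in all 15 alternatives. Of the 6608 calls, between 78.7% (without wild-type replicate 2) and 99.2% (RLE) were called again in the same direction. Counts of genes past 1.5-fold were lower with DESeq2, 207 higher and 95 lower, and with limma-voom, 231 higher and 115 lower, against 371 and 204. Each program used its own test against 1.5-fold, so the counts are not from 1 test, and the cause was not tested. With 1 library left out they ranged from 268 to 395 and from 144 to 199.

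Of the gene lists, 21 were called by camera, 19 to 23 with a library left out, 20 after the length and GC correction, 28 by fry, which asks another question, and 1 with a correlation estimated per list. The latter allows for genes of a list that vary together between replicates. Calls were also lost for lists whose estimated correlation lay below the preset 0.01, fatty acid synthesis at -0.017 and fibroblast markers at -0.023. A lost call therefore does not show that the genes of a list vary together. With a library left out, cancer testis antigens had adjusted p-values from 0.685 to 0.963 and endothelial markers from 0.817 to 0.983, with the direction turned without wild-type replicate 3 (0.793 and 0.921). CD68, not called in any alternative, ranged from -0.011 (without knockout replicate 2, direction turned) to 0.268 on the log2 scale with a library left out. No chromosome was called by camera in any of the 8 alternatives, and chromosome 19 had the smallest unadjusted p, 0.0182, the only 1 of 23 under 0.05.

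Wild-type and knockout libraries share only replicate numbers. Deviations of same-numbered libraries from their group means correlated at -0.029, -0.001 and 0.025 over genes, and not every library correlated best with its own number. With replicate number as a block, 3122 genes were higher and 3119 lower, 354 and 183 past 1.5-fold, 21 lists were called and DUS1L was at -0.511. HSPA6 then had an adjusted p of 0.0608, fibroblast markers of 0.0531 and the interferon response of 0.0362, and no other call of a named gene, fixed list or chromosome changed. The gene families under other observations were not run with it.

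The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 3288 higher and 3320 lower genes and 371 and 204 past 1.5-fold, and the highest other split gave 0. For lists the real split gave 21 and the highest other 15. For chromosomes the real split gave 0 and the highest other 1, so that all 10 gave as many. Each other split sets libraries of both genotypes on each side, in unequal shares. Part of the genotype difference thus stays in the comparison, and the rest widens the spread within the sides. Their counts therefore do not show how many genes or lists would be called without a difference. At these depths, genes given the smallest simulated change were recovered in 42% of cases, so genes not called are not shown to be unchanged. The simulation changed 200 of 16046 genes, against 41.2% of tested genes called in the data. The adjustment of p was thus stricter in the simulation, and recovery in the data may be higher.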

Other observations

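The families and local genes described here, and the tests of leukocyte and epithelial markers, of the length and GC correction on the ribosomal protein and oxidative phosphorylation lists, of the genes around DUS1L and of wild-type cells, were chosen after their values were seen. Among 83 families of protein-coding genes that share the letters of their symbols, 7 were called by camera and none with an estimated correlation. The zinc finger family ZNF, largely KRAB zinc finger repressors, rose in 219 of 469 tested genes and fell in 22 (median log2 fold change 0.32, adjusted p = 2.8e-07, adjusted p = 0.406 with an estimated correlation). On chromosome 19, where many of them lie in clusters, 137 of 234 rose and 3 fell, with a median of 0.46. On other chromosomes 82 of 235 rose and 19 fell, with a median of 0.17. The other 763 protein-coding genes of chromosome 19 had 184 higher and 188 lower genes and a median of -0.01. KLHL genes, adaptors of ubiquitin ligases, had 15 higher and 1 lower of 24 (median 0.27, adjusted p = 0.0123, adjusted p = 0.718 with an estimated correlation). Mitochondrial ribosomal proteins of the large subunit, MRPL, had 22 lower and 2 higher of 49 (median -0.17, adjusted p = 0.0123, adjusted p = 0.718 with an estimated correlation).

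More genes had a count in knockout libraries, 23698 ± 295 against 22880 ± 84, and 23614 ± 231 against 22779 ± 33 once all libraries were thinned to the same total. The smallest p that an exact permutation test allows here is 0.1. A count was seen in all knockout and no wild-type libraries for 195 genes, and the reverse for 64. The 400 olfactory receptor genes, silent outside sensory neurons in general, summed to 15.6, 18.7 and 16.5 CPM in knockout and 11.4, 11.1 and 10.2 CPM in wild-type libraries.

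Heat shock, immediate early, inflammatory and integrated stress response genes were higher in knockout cells. With an estimated correlation, camera called only the heat shock list of these (adjusted p = 0.0226, against 0.107 for each of the others). Transcript length and GC bias as the whole cause is argued against, since after that correction the smallest of the 4 list medians was 0.589. Leukocytes or epithelial cells in the knockout cultures stay open as a source of the summed rise of 18700 CPM in the 87 genes of the lists. The 9 leukocyte and 15 epithelial markers left out by the count filter, called near silent here, summed to 0.931 and 0.441 CPM more in knockout libraries. That is 0.00733% (SE 0.0023) of the rise, but a marker well expressed in knockout libraries alone would have passed the filter. The share was thus bound to be small and decides nothing. Of the 4 epithelial markers that passed, 2 were higher, KRT7 from 12.2 ± 1.6 to 32.3 ± 6.0 CPM and KRT18 from 455.4 ± 27.6 to 531.9 ± 8.6 CPM, and 1 was lower. The near-silent epithelial sums were 2.53 ± 0.43 and 2.97 ± 0.49 CPM and were not tested. Genes such as HSPA1A, at 583.6 ± 129.8 and 4076 ± 522 CPM, weigh heavily in the summed rise. CSF2 was at 2.69 ± 0.92 and 21.2 ± 3.4 CPM, so the share says even less about the inflammatory list alone. The near-silent leukocyte markers did rise, CD14 from 3, 2 and 0 to 9, 20 and 9 counts, PTPRC from 0, 0 and 1 to 7, 1 and 3 and CD3D from 0 in each to 1, 3 and 1, while the sum of all 13 leukocyte markers, 4 of which A375 cells express as they do 4 of 19 epithelial markers, was at 0.956 times the wild-type level (SE 0.079). A difference in culture state or handling between the lines cannot be told apart from genotype, because every knockout culture is on one side (within groups the heat shock and inflammatory scores correlated at -0.03 over 6 libraries, which decides nothing), and loss of DUS1L and properties of the selected clone both stay open.

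Ribosomal protein and oxidative phosphorylation transcripts were lower by small amounts. The length and GC correction moved the ribosomal protein median from -0.277 (SE 0.016) to -0.203 (SE 0.018) and the oxidative phosphorylation median from -0.235 (SE 0.024) to -0.16 (SE 0.024, adjusted p = 0.000107), with both lists still called at the preset correlation. This argues against that bias as the whole cause only as far as the longest transcript per gene, which the correction uses, is the one expressed. The bias stays open for a part. With an estimated correlation neither list was called before the correction (adjusted p = 0.267 and 0.248) or after it (0.3 and 0.225). The bound used, a corrected median below -0.1 by more than 2 SE, replaced one of -0.15 after the values were seen, and by the earlier bound the oxidative phosphorylation list would be undecided. Each SE was taken over the genes of a list as if they were independent, although their estimated correlations were 0.432 and 0.193. The bound thus leaves out noise that the genes share between cultures. A shift of reads to pseudogenes is argued against, since 1514 annotated ribosomal protein pseudogenes did not gain what the genes lost: their change was -0.245% of that loss, from 352.4 ± 7.7 to 319.4 ± 13.2 CPM, and an effect of the genotype or of the clone stays open.

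DUS1L itself was at 70.2% of its wild-type level. A lower copy number or silencing of the whole segment as the cause is argued against by the 47 neighbours within 1 Mb at 5 CPM or more. Their median was -0.183 (SE 0.063, taken over genes as if independent) with 11 higher and 22 lower, and -0.072 after the length and GC correction. Even so, 4.29% of 4125 windows of 20 or more genes had a median as low as the uncorrected one. The stretch of 8 genes from CENPX to FASN had a median of -0.388. After the length and GC correction its genes other than DUS1L had a median of -0.261 (SE 0.112, taken in the same way) against -0.494 for DUS1L. Wild-type cells as the source of all DUS1L transcript left are argued against, since they would bring at least that share of each of their transcripts, and 155 genes were lower by more than the fall of DUS1L plus 2 SE, a bound of 64.3% of wild-type (glmTreat, adjusted p under 0.05). A smaller share of wild-type cells, an edited transcript that is partly stable and a local effect on the stretch stay open, since gene counts do not show the edited site.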
